A study of Mus musculus with 72 samples.

How the data were processed

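Messenger RNA was measured by RNA sequencing in punches of the dorsal hippocampus of C57Bl/6J mice. Zeitgeber time (ZT) counts hours from lights on. At each of 6 times, ZT1, ZT5, ZT9, ZT13, ZT17 and ZT21, 1 group was trained in object location memory (OLM), a task that depends on the hippocampus, and killed 60 min after training. A homecage (HC) group of naive mice was taken at the same 6 times. The 12 groups held 6 libraries each, 72 in all, and the group of each library was read from its labels. The labels do not say in so many words that each library came from a different mouse, so p-values measure the spread between these libraries. RNA was isolated with RNeasy kits and libraries were built with the Illumina Stranded mRNA Prep kit, per the labels.

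The values used are raw counts of reads per gene that the authors deposited, 1 column per library. No column belonged to a sample outside the series (0 columns). Reads were counted with featureCounts on genome build GRCm38, with FastQC for quality checks and DESeq2 for differential expression, per the submitters' processing notes. The aligner, the tool versions and the strand setting of the counting are not given in the sources used here. For genes that overlap another gene on the opposite strand, such as Dlx1as, that missing setting leaves open which of the pair was counted. Hspa1a and Hspa1b are nearly identical in sequence, so how their reads were divided is also uncertain. Gene symbols came from a mouse gene name table by Ensembl identifier, which named 54723 of the 54752 genes, and coordinates came from the deposited gene annotation.

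Library totals ran from 19.2 to 28.6 M counts (median 22.2 M, where M is 10 to the power of 6), and group means from 20.9 M (HC, ZT13) to 25 M (OLM, ZT17). Within groups, pairs of libraries correlated at 0.957 to 0.992. No pair looked like 1 RNA sequenced repeatedly, because the lowest chi-square per degree of freedom over the 180 within-group pairs was 6.09. A gene counted a few times per library is measured poorly at this depth, which is the case for Egr2 and Lcn2 in homecage mice.

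Differential expression used edgeR 4.0.16 in R 4.3.3 with TMM normalization, the filterByExpr filter, which kept 17903 genes, a robust quasi-likelihood fit of the 12 group means to all 72 libraries and F tests. Values per group are CPM, counts scaled to a common library total, as mean ± SD with n libraries, and the standard error (SE) of a log2 fold change is the fold change divided by the square root of its F. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over all genes of that comparison. The comparisons were training against homecage at each time, the average of those 6 effects, their difference between times, their difference between day (ZT1, ZT5, ZT9) and night (ZT13, ZT17, ZT21), and time of day within each arm. Rhythms were cosine fits with a 24 h period to the 36 libraries of each arm, and the amplitude is the log2 height of the peak above the fitted mean. Night minus day within each arm was added after seeing the data.

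In total, 29 gene lists were fixed before the data were examined. They cover the core clock, clock output, immediate early transcription factors, activity-regulated effectors, MAPK feedback regulators, glucocorticoid-responsive genes, cytosolic and endoplasmic reticulum (ER) chaperones, cold-inducible RNA-binding proteins, histone deacetylases, histone acetyltransferases and methyltransferases, glutamate receptors, markers of hippocampal cell types, vessels, choroid plexus, thalamus and neocortex, and blood, mitochondrial and sex chromosome transcripts. Some genes sit in more than 1 list, such as Per1 and Tsc22d3 among the glucocorticoid-responsive genes. Lists were tested with camera (limma 3.58.1) on 8 contrasts, 232 tests adjusted together, and on the night minus day contrast of each arm, adjusted apart, first with a preset correlation between genes and then with the correlation estimated from each list, with fry beside them. Of the 232 the preset test called 80 and the estimated one 40, and the text leads with the estimated one. Counts adjusted over the list alone use the genes of that list as the family.

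Genes are named in the text by a rule. The 12 core clock genes and Fos, Arc, Egr1 and Nr4a1 were to be given in each training comparison whatever their result, the core clock genes that were not called as a range. Other genes come from the smallest p-values in each direction or within a list, and among these the ones that kept their call when single libraries were left out were preferred. The 246 results of the 90 named genes went through each alternative that applied to their comparison.

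The code was tried on counts simulated from each gene's mean and spread, with changes of known size in 50 genes per fold. At 1.5-fold, 70% were called at ZT1, 66% at ZT5, 68% at ZT9, 60% at ZT13, 74% at ZT17 and 58% at ZT21, among 17749 simulated genes. At 1.2-fold the same designs called 20%, 34%, 22%, 20%, 26% and 14%. Unchanged genes called at the 6 times were 8, 2, 3, 7, 7 and 0. In a second simulation the day against night design called 84% at 1.5-fold with 13 unchanged genes, and the interaction design 72% with 15. A homecage rhythm with an amplitude of 0.4 was called for 82% of genes by the cosine fit with 8 unchanged genes, and for 78% by the time of day test with 4. DESeq2 on the 12 ZT1 libraries called 70% at 1.5-fold. The list test with the preset correlation called a list of raised genes and 0 of 28 random lists. Simulated genes varied independently of each other, so this does not check false list calls in real libraries. In redrawn splits of the real libraries the preset test gave a median of 56 calls (24 to 80).

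Alternatives fixed in advance were RLE factors, no filter, DESeq2 1.42.0, library run as a covariate (5 runs of library numbers in the titles), 3 surrogate variables from sva 3.50.0, a fit that is not robust, the 12 libraries of a time alone, each library left out in turn, a minimum change of 1.2-fold, a cohort covariate for rhythms and within-cohort differences for time of day. Cohorts were inferred from sample numbers in the titles that run together, ZT1 with ZT13, ZT5 with ZT17 and ZT9 with ZT21. Single trained libraries at ZT1, ZT9 and ZT13 carry numbers outside those runs and were assigned by their time. After seeing the data, 2 more were added, namely 5 tissue marker scores as covariates and a fit without the 18 libraries richest in choroid plexus transcripts. Arms were also redrawn within times, and times within arms, in 100 splits counting the real one. Splicing, transcript isoforms and sequence variants were left out because only counts per gene were used.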

Results

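At ZT1, early in the day, the question was which transcripts of the dorsal hippocampus differed 60 min after object location training. Egr2, an activity-induced transcription factor (ENSMUSG00000037868, chromosome 10, 67535475 to 67542188, GRCm38), rose from 0.746 ± 0.25 CPM in homecage mice to 4.90 ± 1.5 CPM in trained mice (n = 6 and 6, log2 fold change 2.70, SE 0.34, adjusted p = 7.71e-07, 6 of 6 trained libraries above the homecage mean). Fos, the classic marker of recently active neurons (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), rose from 5.84 ± 1.6 to 19.4 ± 4.8 CPM (log2 1.74, SE 0.27, adjusted p = 4.97e-05). Per1, a clock gene that also answers to stimulation (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), rose from 63.9 ± 8.4 to 99.4 ± 5.9 CPM (log2 0.64, SE 0.09, adjusted p = 1.26e-05). Arc, a synaptic effector (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), rose from 112 ± 20 to 226 ± 56 CPM (log2 1.02, SE 0.23, adjusted p = 0.00906). For Fos, Per1 and Arc, too, 6 of 6 trained libraries lay above the homecage mean. Of 17903 genes, 148 were called higher and 64 lower after training.

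Of 24 immediate early transcription factors measured at ZT1, 7 were called higher (14 adjusted over the list alone, adjusted p = 0.00032, median log2 0.44). Among them were Fosb (1.01, SE 0.14) and Junb (0.69, SE 0.13). Nr4a1 rose by 0.89 (adjusted p = 0.0221, lost in 3 of 12 fits without 1 library). Egr1 was not past the threshold (0.71, SE 0.22, adjusted p = 0.109, 5 of 6 trained libraries above). Of 19 glucocorticoid-responsive genes 7 were higher (9 over the list alone, adjusted p = 0.00087). The kinase Sgk1 rose by 0.97 (SE 0.19), the NF-kappaB inhibitor Nfkbia by 0.63 (SE 0.11) and Tsc22d3 by 0.68 (SE 0.15). Of 13 MAPK feedback regulators 3 were higher and 1 lower (5 and 1 over the list alone, adjusted p = 0.012). Spry4 rose by 0.67 and Dusp5 by 0.96, while Spry2 fell by 0.29 (SE 0.07, adjusted p = 0.0268). Activity-regulated effectors (6 of 33 higher, 7 over the list alone, adjusted p = 0.0011), cytosolic heat shock chaperones (2 of 19, 10 over the list alone, adjusted p = 0.027) and endoplasmic reticulum chaperones (4 of 18, 13 over the list alone, adjusted p = 0.027) moved the same way. Dnajb1 rose by 0.48 and the ER chaperone Hspa5 by 0.53. Tac2, a tachykinin precursor abundant in the habenula, fell from 5.38 ± 4.6 to 2.04 ± 0.71 CPM (log2 -1.39, SE 0.30, adjusted p = 0.00574). Tab1, an adaptor of the TAK1 kinase, fell by 0.35 (SE 0.07, adjusted p = 0.00312). Spry2 lost its call in 4 of 12 fits without 1 library, Dusp5 in 2, and Hspa5 and Tac2 in 1. Without single ZT1 libraries the count ran from 112 to 388, and without the 18 libraries richest in choroid plexus transcripts, a fit added after seeing the data, it was 19.

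At ZT5, mid-day, training was followed by a similar response. Arl4d, a small GTPase, rose by 0.90 (n = 6 and 6, SE 0.11, adjusted p = 5.15e-08). Egr2 rose from 0.673 ± 0.44 to 4.26 ± 1.3 CPM (log2 2.63, SE 0.35, adjusted p = 1.31e-06) and Sgk1 (ENSMUSG00000019970, chromosome 10, 21882184 to 21999903) from 74.3 ± 11 to 178 ± 46 CPM (log2 1.26, SE 0.19, adjusted p = 1.56e-05). Per2, the partner of Per1 in the clock, rose by 0.65 (SE 0.09, adjusted p = 1.36e-06). Per1 rose from 73 ± 7.9 to 109 ± 14 CPM (log2 0.58, SE 0.09, adjusted p = 0.000119). Fos rose by 1.57 (SE 0.27, adjusted p = 0.000347). In each of these 6 genes 6 of 6 trained libraries were above the homecage mean. In total 108 genes were called higher and 18 lower. Of the higher ones 58 were also called higher at ZT1 (148 × 108 / 17903 = 0.893 expected by chance).

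Of 24 immediate early transcription factors measured at ZT5, 11 rose (16 over the list alone, adjusted p = 2.2e-05). They included Fosb (0.97), Egr4 (0.89) and Egr1 (0.89, adjusted p = 0.0348, lost in 8 of 12 fits without 1 library). Nr4a1 was not past the threshold (0.81, adjusted p = 0.0547). Of 13 MAPK feedback regulators 5 rose (8 over the list alone, adjusted p = 5.4e-05), among them Spry4 by 0.62 (SE 0.12, adjusted p = 0.00129). Among 19 glucocorticoid-responsive genes 6 rose (9 over the list alone, adjusted p = 0.00039), with Ddit4 at 0.53 and Nfkbia at 0.69. Activity-regulated effectors (4 of 33, 6 over the list alone, adjusted p = 0.00047) included the postsynaptic scaffold Homer1 at 0.52 (SE 0.12, adjusted p = 0.0132) and Arc at 0.90 (adjusted p = 0.0378, lost in 8 of 12 fits without 1 library). Heat shock chaperones followed (3 of 19, 12 over the list alone, adjusted p = 0.016), with the co-chaperone Chordc1 at 0.42. The ER chaperones had adjusted p = 0.10 with an estimated correlation (2 of 18, 5 over the list alone). Among genes that fell were Kyat1, which makes kynurenic acid (-0.30, SE 0.07, adjusted p = 0.00984), and Clec14a, an endothelial surface protein (-0.72, SE 0.16, adjusted p = 0.0125). Tipin, a replication fork protein, fell by 0.43 (SE 0.10, adjusted p = 0.0132). Tipin lost its call in 2 of 12 fits without 1 library, and Homer1, Chordc1, Kyat1 and Clec14a in 1. The count ran from 56 to 132 without single ZT5 libraries, and was 51 without the choroid-rich libraries.

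**Figure D1:**
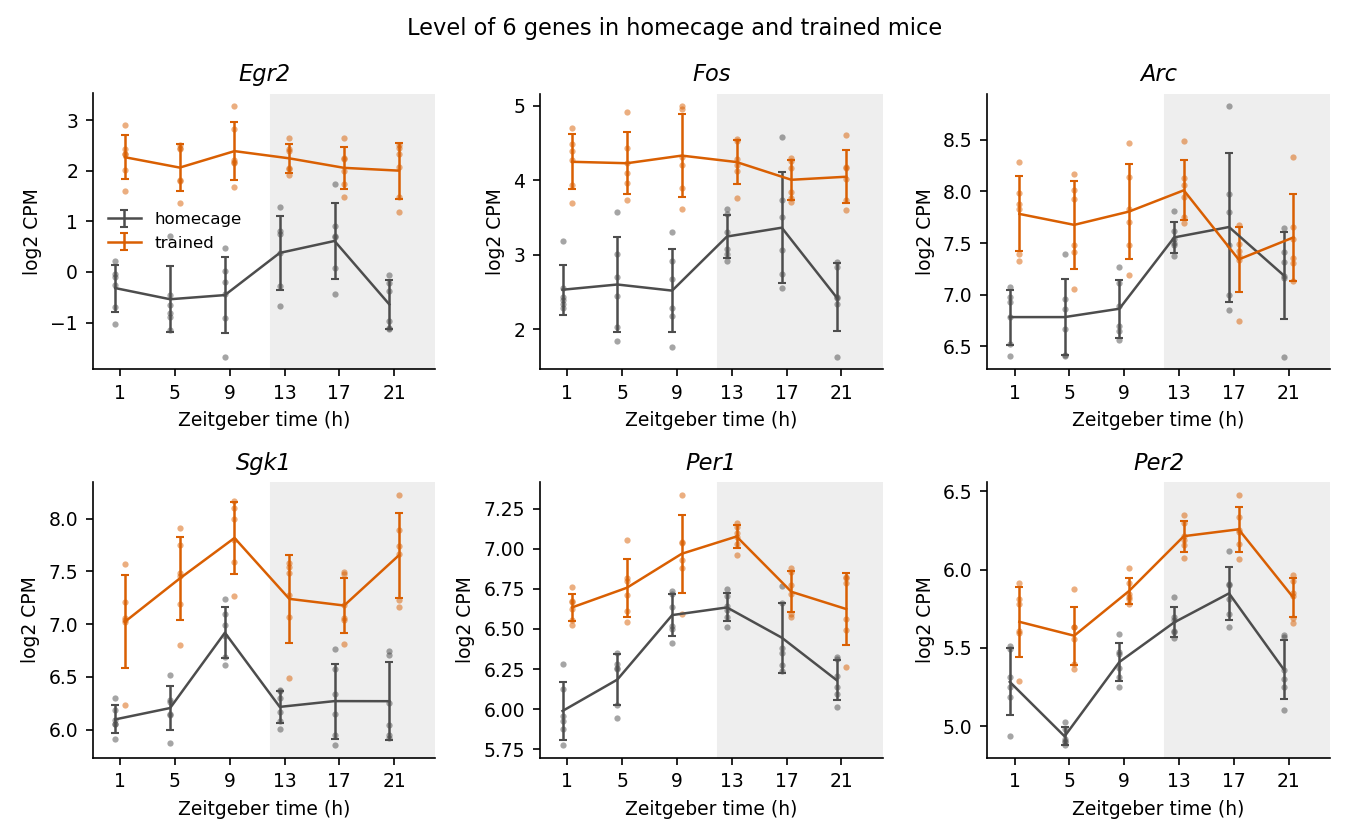
Expression (log2 CPM, vertical) of Egr2, Fos, Arc, Sgk1, Per1 and Per2 in homecage and trained mice against zeitgeber time (h, horizontal, night shaded), 1 point per library (n = 6 per group) with mean ± SD. The means of Egr2, Sgk1, Per1 and Per2 were higher after training at each time, with some overlap of single libraries, and the mean of Arc was lower after training at ZT17.

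At ZT9, late in the day, Fosb, an activity-induced AP-1 subunit (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), rose by 1.26 (n = 6 and 6, SE 0.14, adjusted p = 1.59e-08). Arl4d rose by 0.90 (SE 0.10, adjusted p = 2.0e-08) and Egr2 from 0.719 ± 0.38 to 5.50 ± 2.4 CPM (log2 2.93, SE 0.34, adjusted p = 2.34e-08). P4ha1, a collagen prolyl hydroxylase subunit, rose by 0.63 (SE 0.08, adjusted p = 1.12e-06), and Fos by 1.83 (SE 0.27, adjusted p = 2.58e-05), all 5 genes in 6 of 6 trained libraries. Per2 rose by 0.45 (SE 0.09, adjusted p = 0.00218). Per1 rose from 96.3 ± 8.6 to 127 ± 21 CPM (log2 0.39, SE 0.09, adjusted p = 0.026, lost in 5 of 12 fits without 1 library). Here 52 genes were called higher and 10 lower.

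Of 24 immediate early transcription factors at ZT9, 12 rose (15 over the list alone, adjusted p = 1.7e-06). Among them were the orphan receptor Nr4a2 (0.80, SE 0.15), Junb (0.68, SE 0.13), Egr1 (1.07, SE 0.22, adjusted p = 0.0081, lost in 1 of 12 fits without 1 library) and Nr4a1 (0.89, adjusted p = 0.0444, lost in 10 of 12 such fits). Activity-regulated effectors rose as a list (6 of 33, 9 over the list alone, adjusted p = 7.9e-06). Homer1 rose by 0.59 (SE 0.12, adjusted p = 0.00342) and Arc by 0.98 (adjusted p = 0.0276, lost in 6 of 12 such fits). The MAPK feedback list (2 of 13, 7 over the list alone, adjusted p = 0.00011) moved up with Spry4 at 0.56. So did the glucocorticoid-responsive list (5 of 19, 9 over the list alone, adjusted p = 0.0014) with Sgk1 at 0.91. Heat shock chaperones (1 of 19, 12 over the list alone, adjusted p = 0.007) and ER chaperones (2 of 18, 14 over the list alone, adjusted p = 0.0063) rose as lists, and Hspa5 rose by 0.62 (SE 0.12, adjusted p = 0.00218). Tab1 fell by 0.36 (SE 0.07, adjusted p = 0.00369) and the death ligand gene Tnfsf10 by 0.87 (SE 0.20, adjusted p = 0.0186, lost in 4 of 12 such fits). Without single ZT9 libraries the count was 37 to 65, and without the choroid-rich libraries 11.

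At ZT13, the first hour of night, 16 genes were called, each of them higher after training, with 890 genes at unadjusted p under 0.05. Fosb rose by 1.07 (n = 6 and 6, SE 0.14, adjusted p = 3.31e-06) and Per2 by 0.55 (SE 0.09, adjusted p = 0.000156). Sgk1 rose from 74.5 ± 7.8 to 156 ± 39 CPM (log2 1.06, SE 0.19, adjusted p = 0.0011) and Egr2 from 1.35 ± 0.66 to 4.73 ± 0.97 CPM (log2 1.81, SE 0.32, adjusted p = 0.00145), all 4 in 6 of 6 trained libraries. Per1 rose from 99.4 ± 6.0 to 135 ± 6.7 CPM (log2 0.44, SE 0.09, adjusted p = 0.0209, lost in 5 of 12 fits without 1 library). Fos (1.0, adjusted p = 0.22), Nr4a1 (0.67, adjusted p = 0.511) and Arc (0.47, SE 0.23, adjusted p = 0.962) were not past the threshold. Egr1 passed (0.98, adjusted p = 0.0484) but was lost in 11 of 12 such fits.

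The glucocorticoid-responsive list led at ZT13 (4 of 19 higher, 16 over the list alone, adjusted p = 6.1e-06), with Sgk1 and Nfkbia (0.56, lost in 4 of 12 fits without 1 library) among its genes. It was followed by the activity-regulated effectors (2 of 33, 2 over the list alone, adjusted p = 4.6e-05) and the immediate early factors (5 of 24, 12 over the list alone, adjusted p = 8e-05) with Egr4 at 0.88. The MAPK feedback regulators (0 of 13, 2 over the list alone, adjusted p = 0.0049), the ER chaperones (0 of 18, 11 over the list alone, adjusted p = 0.013) and the interneuron markers (0 called, 3 over the list alone, adjusted p = 0.049) were also higher. Heat shock chaperones had adjusted p = 0.15 with an estimated correlation. Thalamus and habenula markers were lower (median log2 -1.22, 7 over the list alone). Prkcd, a kinase of the thalamus, was at -1.33 (SE 0.40, adjusted p = 0.412, 6 of 6 trained libraries below), and the list had adjusted p = 0.30 with an estimated correlation. The count was 6 to 13 without single ZT13 libraries and 9 without the choroid-rich ones. That second fit kept all 6 libraries of both ZT13 groups, so its lower count came from leaving out libraries of other times.

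At ZT17, mid-night, the fewest genes were called, 5 higher and 0 lower, with 811 at unadjusted p under 0.05 with edgeR (17 called with DESeq2). Without homecage replicate 1 the count was 22, more than the 16 at ZT13 with all libraries, so this rank depends on that library. Lfng, a glycosyltransferase that modifies Notch receptors (ENSMUSG00000029570, chromosome 5, 140607320 to 140615545), rose from 14.2 ± 2.7 to 22.3 ± 1.7 CPM (n = 6 and 6, log2 0.65, SE 0.10, adjusted p = 0.000123). Fosb rose from 8.23 ± 1.3 to 14.8 ± 2.2 CPM (log2 0.85, SE 0.14, adjusted p = 0.000559), both in 6 of 6 trained libraries. Sgk1 (0.89, SE 0.18), Per2 (0.41, SE 0.09) and Lcn2, an acute-phase iron carrier protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, log2 5.38, SE 1.10, 4 of 6 trained libraries above), had adjusted p = 0.0382, and lost the call in 6, 9 and 7 of 12 fits without 1 library. Per1 was not past the threshold (0.28, SE 0.09, adjusted p = 0.683, 6 of 6 trained libraries above). Nor were Fos (0.49, SE 0.26), Egr1 (0.25, SE 0.22) and Nr4a1 (-0.16, SE 0.22). Arc was at 225 ± 120 CPM in homecage and 165 ± 32 CPM in trained mice (log2 -0.45, SE 0.23).

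The chaperone lists still moved at ZT17. ER chaperones were higher as a list (0 of 18 called, 14 over the list alone, median log2 0.27, adjusted p = 0.00087). In that list Pdia6 was at 0.40 (SE 0.09, adjusted p = 0.0848) and Hyou1 at 0.28 (SE 0.07, adjusted p = 0.081), and heat shock chaperones moved with them (0 of 19, 5 over the list alone, adjusted p = 0.027). The glucocorticoid-responsive genes (1 of 19, 9 over the list alone, adjusted p = 0.00025), the immediate early factors (1 of 24, 4 over the list alone, adjusted p = 0.022) and the effectors (0 of 33, 1 over the list alone, adjusted p = 0.034) were also higher. Cirbp (-0.30, SE 0.11) and Rbm3 (-0.25, SE 0.11), RNA-binding proteins induced by cold, were lower over their list alone, but the list had adjusted p = 0.053 with an estimated correlation. The count ran from 2 to 22 without single ZT17 libraries and was 5 without the choroid-rich ones, 3 of them the same genes.

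At ZT21, late at night, 34 genes were higher and 8 lower. Arl4d rose by 0.90 (n = 6 and 6, SE 0.10, adjusted p = 5.39e-08) and Egr2 from 0.583 ± 0.22 to 4.14 ± 1.4 CPM (log2 2.82, SE 0.35, adjusted p = 2.32e-07). Sgk1 rose from 79.3 ± 21 to 208 ± 58 CPM (log2 1.39, SE 0.19, adjusted p = 1.93e-06) and Fos from 5.51 ± 1.6 to 16.9 ± 4.3 CPM (log2 1.61, SE 0.27, adjusted p = 0.00039), all 4 in 6 of 6 trained libraries. Per2 rose by 0.45 (SE 0.09, adjusted p = 0.00225). Per1 rose from 72.7 ± 6.2 to 99.6 ± 15 CPM (log2 0.45, SE 0.09, adjusted p = 0.00602). Icam1, an adhesion molecule of activated endothelium (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817), rose by 2.28 (SE 0.39, adjusted p = 0.00039, 5 of 6 trained libraries above). Arc (0.38, adjusted p = 0.536), Egr1 (0.71, adjusted p = 0.20) and Nr4a1 (0.47, adjusted p = 0.413) were not past the threshold.

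Glucocorticoid-responsive genes were the most affected list at ZT21 (8 of 19 higher, 12 over the list alone, adjusted p = 0.00025), with Nfkbia at 0.76, Ddit4 at 0.50 and Errfi1 at 0.42. Immediate early factors (5 of 24, 10 over the list alone, adjusted p = 0.0025) and effectors (1 of 33, 5 over the list alone, adjusted p = 0.0044) were higher too. So were MAPK feedback regulators (1 of 13, 3 over the list alone, adjusted p = 0.027) and heat shock chaperones (2 of 19, 11 over the list alone, adjusted p = 0.027), with the small heat shock protein Hspb1 at 0.96 (SE 0.20, adjusted p = 0.00966). Xbp1, which drives ER chaperone transcription, rose by 0.43 (SE 0.10, adjusted p = 0.0206), while the ER list had adjusted p = 0.12 with an estimated correlation. The microglial receptor P2ry13 fell by 0.37 (SE 0.08, adjusted p = 0.0119) and the taurine transporter Slc6a6 by 0.28 (SE 0.06, adjusted p = 0.0209). Slc6a6 lost its call in 5 of 12 fits without 1 library, P2ry13 in 4, Xbp1 in 3 and Hspb1 in 2. Regrouping the 12 libraries gave up to 557 calls at ZT21 in 100 splits, so this count is uncertain, although 24 of the 34 raised genes were also raised at ZT1 (148 × 34 / 17903 = 0.281 expected by chance). It ran from 16 to 97 without single libraries and was 9 without the choroid-rich ones.

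**Figure D2:**
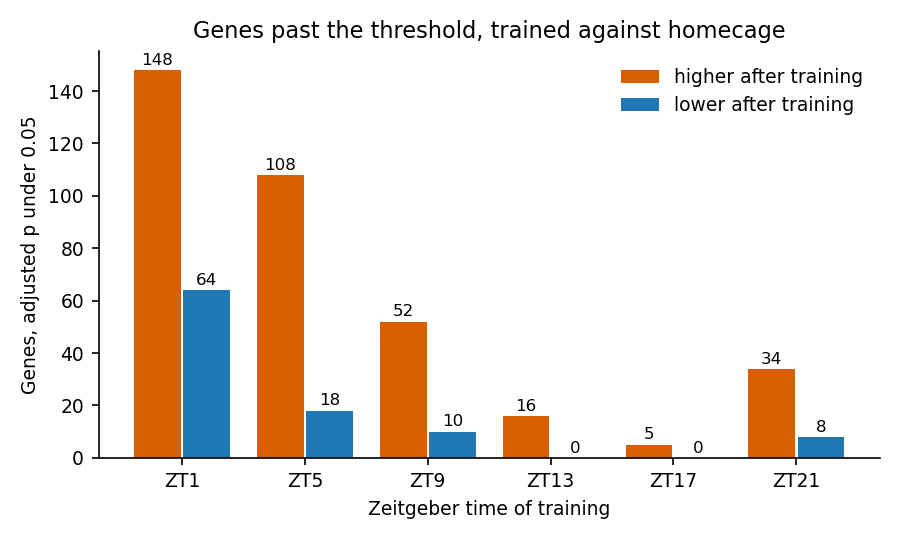
Number of genes (vertical) called higher or lower after training at each zeitgeber time (horizontal), 6 trained against 6 homecage libraries each, adjusted p under 0.05. Calls were most numerous at ZT1 and fewest at ZT17.

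Averaged over the 6 times, training raised 794 genes and lowered 486 (median absolute log2 0.15), and 871 of these 1280 had the same sign at all 6 times. Choosing genes by this average favors such agreement, and 997 of the 1280 were called at no single time. Fosb (1.01, SE 0.06, adjusted p = 3.75e-22), Arl4d (0.75, SE 0.04, adjusted p = 3.75e-22) and Egr2 (2.38, SE 0.14, adjusted p = 5.61e-22) had the smallest p-values. P4ha1 (0.49, SE 0.03, adjusted p = 4.09e-18) and Sgk1 (1.08, SE 0.08, adjusted p = 8.55e-18) came next. Fosb, Per2 and Sgk1 were called higher at each of the 6 times, and Arl4d, Egr2, Egr4, Nfkbia, P4ha1 and Per1 at 5. Arc rose by 0.55 (SE 0.09, adjusted p = 1.92e-05), Egr1 by 0.77 (adjusted p = 3.09e-09) and Nr4a1 by 0.59 (adjusted p = 1.48e-06). Fos rose by 1.36 to 1.43 over 8 alternative fits (largest adjusted p = 4.56e-11). Without the choroid-rich libraries 748 genes were called.

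**Figure D3:**
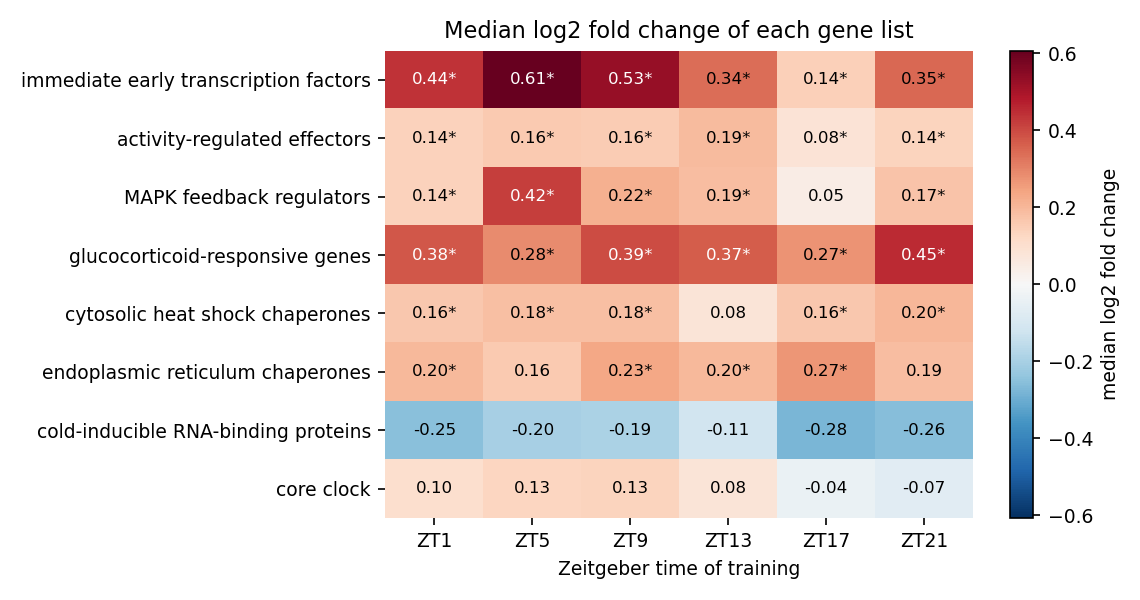
Median log2 fold change after training (color and printed value) of gene lists (vertical) at each zeitgeber time (horizontal), 6 trained against 6 homecage libraries per time, with a star where adjusted p was under 0.05 with an estimated correlation. The immediate early and MAPK feedback medians were lowest at ZT17, when the ER chaperone median was highest.

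By list, the average effect called 17 of 24 immediate early factors (17 over the list alone, adjusted p = 3.1e-07), 15 of 19 glucocorticoid-responsive genes (16 over the list alone, adjusted p = 3.1e-07) and 11 of 33 effectors (19 over the list alone, adjusted p = 3.1e-07) higher. It also raised 7 of 13 MAPK feedback regulators (8 over the list alone, adjusted p = 1.2e-05), 15 of 19 heat shock chaperones (18 over the list alone, adjusted p = 0.00025) and 15 of 18 ER chaperones (15 over the list alone, adjusted p = 0.00025). Tsc22d3, the glucocorticoid-induced leucine zipper gene, rose by 0.52 (adjusted p = 1.3e-09). Hspa5 rose by 0.49 (SE 0.05, adjusted p = 5.69e-12), Dnajb1 by 0.35 (adjusted p = 7.99e-11) and Xbp1 by 0.35 (adjusted p = 5.37e-10). Both cold-inducible genes fell, Cirbp by 0.29 (SE 0.04, adjusted p = 3.39e-06) and Rbm3 by 0.15 (SE 0.04, adjusted p = 0.0216, lost in 1 of 8 alternatives with adjusted p = 0.311), with adjusted p = 0.027 for the list. Among other genes that fell were P2ry13 (-0.28, SE 0.03, adjusted p = 1.25e-09), Tipin (-0.30, SE 0.04, adjusted p = 3.45e-08), Tab1 (-0.20) and Chpf2 (-0.22), which helps build chondroitin chains. Histone deacetylases did not move as a list (median log2 -0.01, 1 lower). That gene, Hdac3, a brake on memory formation, fell by 0.07 (SE 0.02, adjusted p = 0.00576) and had adjusted p = 0.087 without the choroid-rich libraries, with its size between -0.069 and -0.064 in each alternative.

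Within the core clock, training raised Per1, Per2 and, on average, Cry1, and the other core clock genes were not past the threshold. On average Per2 rose by 0.48 (SE 0.04, adjusted p = 1.91e-17), Per1 by 0.46 (SE 0.04, adjusted p = 3.31e-15) and Cry1 by 0.17 (SE 0.04, adjusted p = 0.0019). The other 9 core clock genes lay between -0.09 and 0.04 (smallest adjusted p = 0.107). At single times the core clock genes that were not called lay between -0.09 and 0.27 at ZT1 (10 genes, smallest adjusted p = 0.522), -0.07 and 0.23 at ZT5 (10, 0.379), and -0.04 and 0.21 at ZT9 (10, 0.546). At night they lay between -0.50 and 0.26 at ZT13 (10, 0.659), -0.19 and 0.28 at ZT17 (11, 0.683), and -0.18 and 0.17 at ZT21 (10, 0.478). At ZT1 Per2 also rose (0.38, SE 0.09, adjusted p = 0.00799, lost in 2 of 12 fits without 1 library). As a list the core clock had adjusted p = 0.16 with an estimated correlation in the average, and clock output genes 0.25.

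Whether the response to training depended on time of day was tested jointly and as day against night. The joint interaction called 0 genes with edgeR (smallest adjusted p = 0.154, for Tiparp among others; 876 at unadjusted p under 0.05) and 14 with DESeq2. The day against night test called 30 genes with a larger effect by day and 5 with a smaller or more negative one (2227 at unadjusted p under 0.05). Tiparp, an ADP-ribosylating enzyme induced by the aryl hydrocarbon receptor, rose at ZT1 from 11 ± 1.2 to 16.1 ± 1.3 CPM. Its homecage and trained levels at night were 16.2 ± 1.5 and 16.6 ± 2.7 CPM at ZT13, and 13.8 ± 1.6 and 13.4 ± 1.2 at ZT17. At ZT21 they were 13.1 ± 1.0 and 15 ± 1.8, with 6 of 6 trained libraries above the homecage mean. The day against night difference of effects was 0.43 (SE 0.08, adjusted p = 0.00944). Arc had a mean effect of 0.97 by day and 0.14 by night (difference 0.83, SE 0.19, adjusted p = 0.0316). Its ZT17 effect, part of the night mean, ran from -0.57 to -0.11 without single libraries. The day against night difference was not refitted that way. In homecage mice it was higher at night by 0.70 (adjusted p = 0.00039). The splicing kinase Clk1 (0.45, SE 0.08), the GTPase Rab23 (0.21, SE 0.04) and the survival factor Mcl1 (0.19, SE 0.04) differed likewise, and Kyat1 in the other direction (-0.26, SE 0.05).

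For Per1 the day minus night difference was 0.15 (SE 0.08, adjusted p = 0.424) and for Per2 0.03 (SE 0.07, adjusted p = 0.918), so neither passed. No fixed list was called for this difference with an estimated correlation. Immediate early factors had adjusted p = 0.13 (median 0.19, 6 higher and 1 lower over the list alone) and MAPK feedback regulators 0.12. Without the choroid-rich libraries 2 genes were called, although the median difference of the 35 genes was 0.276 there against 0.261 with all libraries. The count rose to 156 with DESeq2 and 159 with library run in the fit. Of the 35, 23 were also called in the average training effect.

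In homecage mice, time of day changed 867 genes, and a 24 h rhythm was called for 1641 of 17372 genes over 36 libraries. Sample numbers in the titles put ZT1 with ZT13, ZT5 with ZT17 and ZT9 with ZT21, so the joint test mixes time with cohort, and within these pairs 842, 350 and 73 genes differed. Dbp, a transcription factor driven directly by the clock (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), ran from 47.3 ± 10 CPM at ZT1 to 114 ± 16 at ZT9 (n = 6 each, amplitude 0.69, peak at 10.9 h, adjusted p = 2.0e-13). The repressor Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333) ran from 125 ± 13 CPM at ZT13 to 55.4 ± 6.7 at ZT21 (amplitude 0.60, peak 10 h, adjusted p = 1.2e-12). Ciart, a circadian repressor, ran from 14.8 ± 1.4 to 4.35 ± 0.73 CPM at the same times (amplitude 0.98, peak 11.3 h, adjusted p = 1.2e-15). Per1 peaked at 12.5 h (amplitude 0.32, adjusted p = 3.6e-07), Per3 at 14.9 h and Per2 at 15.8 h and Cry1 at 17.3 h. Arntl, the activator of the loop, peaked on the opposite side of the cycle at 0.6 h (amplitude 0.36, adjusted p = 2.9e-07). Of the 12 core clock genes 8 were rhythmic, of which Rora lost its call in 5 of 7 alternative fits. Clock (adjusted p = 0.16), Rorb (0.18), Cry2 (0.36) and Npas2 (0.61) were not called.

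**Figure D4:**
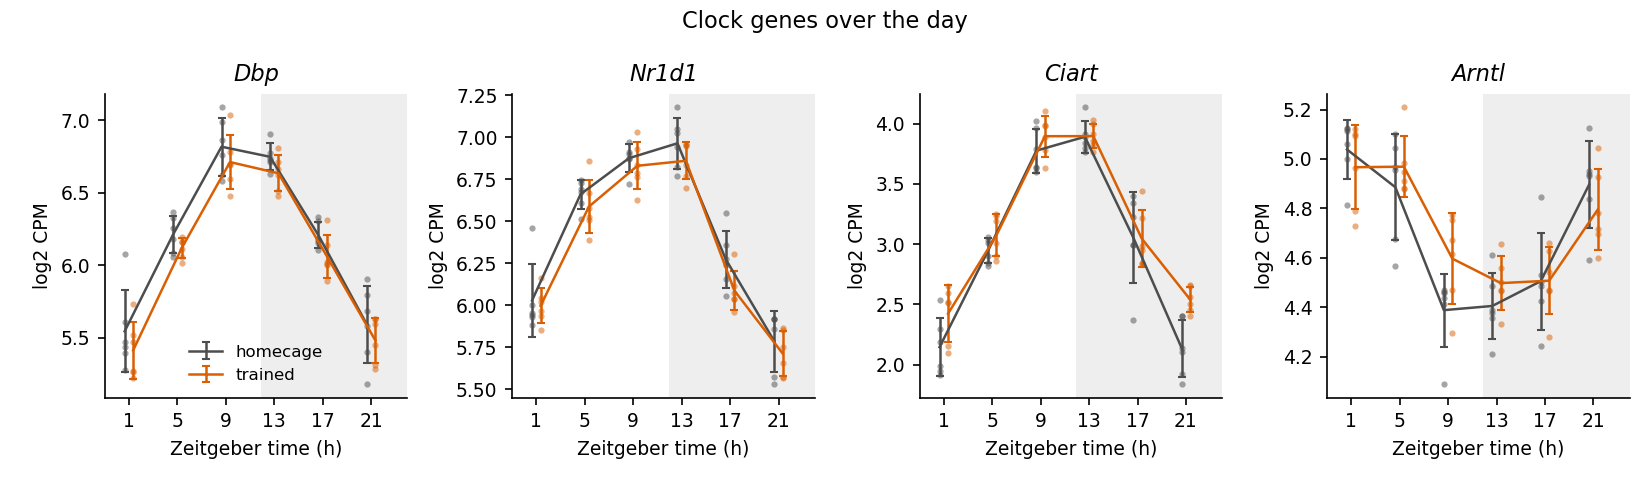
Expression (log2 CPM, vertical) of Dbp, Nr1d1, Ciart and Arntl in homecage and trained mice against zeitgeber time (h, horizontal, night shaded), 1 point per library (n = 6 per group) with mean ± SD. Dbp, Nr1d1 and Ciart were highest around ZT9 to ZT13 in both arms, and Arntl was lowest around then.

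Beyond the clock, homecage rhythms divided by phase. ER chaperones were rhythmic for 12 of 18 genes, with Calr peaking at 21.3 h (amplitude 0.32) and Hsp90b1 at 21.6 h (0.26), and so were 10 of 19 heat shock chaperones. The cold-inducible Rbm3 peaked at 9.8 h (amplitude 0.33), and both genes of its list were rhythmic. Glucocorticoid-responsive genes (11 of 19) included Tsc22d3 at 13.4 h (0.34). Of 24 immediate early factors 6 were rhythmic, of 33 effectors 5, and of 13 MAPK feedback regulators 5. Of 16 histone acetyltransferases and methyltransferases 2 were, and of 14 clock output genes 8, with Hlf at 14.9 h and Tef at 15.6 h. Fmo2, a flavin monooxygenase, had the amplitude 1.06 and peaked at 13.1 h. Of the 1641 rhythms 602 peaked between ZT0 and ZT12 and 1039 between ZT12 and ZT24. Without the choroid-rich libraries 1191 rhythms were called, 987 of them among the 1641, and 571 time of day genes, 483 of them among the 867.

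In trained mice time of day changed 489 genes, and 540 of 17410 genes had a rhythm. Phase was not tested between the arms. Dbp peaked at 10.9 h (amplitude 0.71), Nr1d1 at 9.7 h (0.61) and Ciart at 11 h (0.82). Per1 peaked at 11.1 h (0.23), Per2 at 15.1 h (0.35) and Arntl at 2.1 h (0.28). Of the list, 8 of 12 core clock genes were called. Of 24 immediate early factors 1 was rhythmic, of 13 MAPK feedback regulators 0 and of 33 effectors 2. Rhythms were called for 10 of 18 ER chaperones and 4 of 19 glucocorticoid-responsive genes, and no difference between lists or arms was tested. In all, 250 genes were rhythmic in both arms (1641 × 540 / 17206 = 51.5 expected by chance), and 220 of these peaked within 3 h of each other (median difference 1.34 h). Genes called in homecage mice had a median amplitude of 0.143 there and 0.0842 in trained mice, a comparison that favors the arm in which they were chosen. Genes called in trained mice showed the mirror image, 0.153 against 0.115. Without the choroid-rich libraries 127 rhythms were called in trained mice, 115 of them among the 540, and 138 time of day genes, 129 of them among the 489.

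Between night and day, 765 genes were higher and 446 lower at night in homecage mice, and 47 higher and 13 lower in trained mice, in contrasts added after seeing the data. Arc was higher at night by 0.70 in homecage mice. No list was called with an estimated correlation. In homecage mice ER chaperones (8 higher) had adjusted p = 0.25, heat shock chaperones (5 higher) 0.25, MAPK feedback regulators (3 higher) 0.21 and immediate early factors (4 higher, 1 lower) 0.37. In trained mice ER chaperones (4 higher) had adjusted p = 0.14. Without the choroid-rich libraries 639 genes were called in homecage mice and 9 in trained mice.

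Markers of neighbouring tissue varied between libraries and between groups. Ttr, a choroid plexus transcript, ran from 0.195 to 14100 CPM between libraries, with group medians from 162 (HC, ZT17) to 3641 CPM (OLM, ZT9). Marker lists called at single times with the preset correlation were choroid plexus (median log2 -0.77 at ZT5, -0.13 at ZT9, 1.15 at ZT17 and 0.40 at ZT21) and blood cells (-0.52 at ZT5, 0.62 at ZT9, 0.64 at ZT17 and 0.77 at ZT21). Others were oligodendrocytes (0.35 at ZT1, 0.44 at ZT21), mitochondrial transcripts (0.28 at ZT9, -0.29 at ZT17) and CA1 (0.65 at ZT13). CA3 (-0.16 at ZT13), glutamate receptors (0.08 at ZT13, -0.15 at ZT21), fibroblasts (-0.17 at ZT5), endothelium (-0.16 at ZT17), thalamus (-1.22 at ZT13) and sex chromosome transcripts (-0.12 at ZT21) were also called. None of these calls was kept with an estimated correlation (adjusted p = 0.11 to 0.87), whereas the interneuron list at ZT13 was (median 0.18, adjusted p = 0.049). CA2, dentate granule, astrocyte, oligodendrocyte precursor, microglia and neocortex markers were not called in any contrast.

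Lcn2 and Icam1, which endothelium and glia make when inflamed, were high in part of the trained libraries. Of 36 trained libraries 10 had more Lcn2 than any homecage library (0.597 CPM at most), up to 17.5 CPM, and they came from 3 of the 6 times. For Icam1 9 trained libraries lay above the highest homecage library (5.01 CPM), up to 24.3 CPM, and 7 libraries were high in both genes. The trained ZT17 libraries high in Lcn2 had more Icam1 than each ZT17 homecage library but less than the highest homecage library of all times. Over the 36 trained libraries log2 Lcn2 correlated with Icam1 (r = 0.721, permutation p = 2e-05, adjusted p = 4e-05), with the neutrophil protein gene S100a9 (r = 0.854, p = 1e-05, adjusted p = 3e-05) and with Bcl3, a regulator of NF-kappaB (r = 0.808, p = 1e-05, adjusted p = 3e-05). The haemoglobin gene Hbb-bs correlated less (r = 0.436, adjusted p = 0.0116). With each time centred the values were 0.757 for Icam1, 0.833 for S100a9 and 0.782 for Bcl3. Within single times r varied widely, from -0.146 to 0.969 for Icam1, 0.336 to 0.998 for S100a9 and -0.0149 to 0.954 for Bcl3. The smallest p that 100000 permutations can give is 1e-05, and these genes were chosen after Lcn2 was seen.

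**Figure D5:**
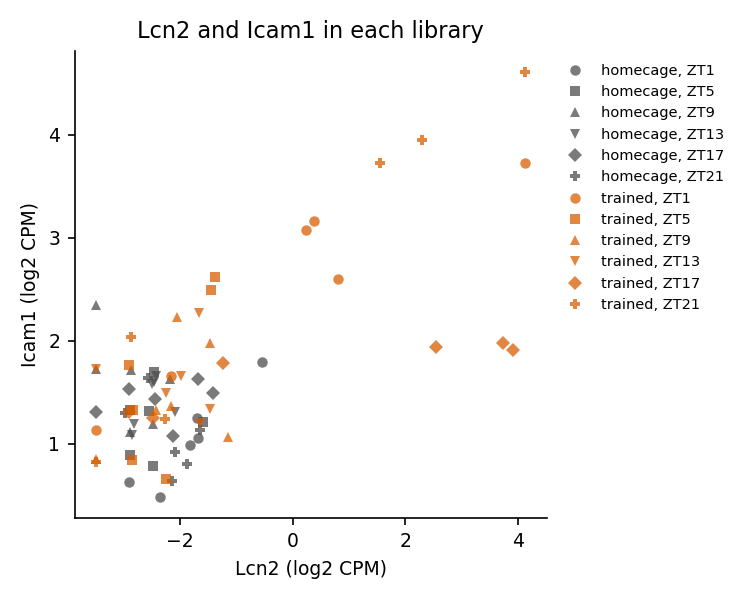
Lcn2 against Icam1 (log2 CPM on both axes) in 36 homecage and 36 trained libraries, 1 point each, with a symbol for each zeitgeber time. The libraries high in both genes came from trained mice.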

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

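The splits of the libraries were laid down before the results were seen, except those of the list tests with an estimated correlation and of the genes raised at both ZT21 and ZT1. The night minus day contrasts that some splits were applied to were themselves added after seeing the data. The other tests of the patterns below were chosen after the result was seen, apart from the split of the training and night relation and the choroid test of Lcn2.

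For 11 measured genes each of 132 groups of 6 libraries was searched for a library far from its group, and 9 were found. That is little above the rate of about 1 in 20 groups that such a search gives by chance. Without training at ZT1, Fos was 9.02 CPM in replicate 5 (4.82 to 5.77 in the other libraries), and in replicate 3 both Dbp (67.3 CPM against 38.6 to 48.7) and Nr1d1 (88 CPM against 58.9 to 64.1) were high, a pair that moves together in the clock. Egr2 was 1.55 CPM in replicate 2 of homecage ZT5 (others 0.363 to 0.639), and Arc 322 CPM in replicate 3 of trained ZT21 (others 140 to 201). Lcn2 stood apart in 4 groups: 0.597 CPM in replicate 1 of homecage ZT1 (others 0.0442 to 0.221), 17.3 CPM in replicate 5 of trained ZT1 (others 0 to 1.66), 0.241 CPM in replicate 1 of homecage ZT5 (others 0.0453 to 0.0912) and 17.5 CPM in replicate 2 of trained ZT21 (others 0 to 4.81). The homecage Lcn2 values of 0.597 and 0.241 CPM rest on only 12 and 5 reads. All libraries stayed in each fit.

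The other results marked for a closer look are the genes whose response to training differed between day and night, 35 in all, because they bear on the biology of timing while the joint test called 0. Tiparp (0.43), Rab23 (0.21), Clk1 (0.45), Trmt1l (0.23), Mcl1 (0.19), Spty2d1 (0.29), Ppp1r15b (0.17), Mex3c (0.25), Zfp638 (0.28), Mis12 (0.25) and Arc (0.83) responded more by day, and Kyat1 (-0.26) had a mean effect of -0.18 by day and 0.08 by night. Their adjusted p-values were 0.00944 for Tiparp, Rab23 and Clk1, 0.0129 for Trmt1l and Mcl1, 0.0133 for Spty2d1, 0.0152 for Kyat1, 0.0267 for Ppp1r15b and Mex3c, 0.0275 for Zfp638 and Mis12, and 0.0316 for Arc.

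The smaller training effect at night could be noise, tissue content or a higher homecage level at night, and the zeitgeber groups of the design make the last of these a biological explanation. Over the 794 genes raised on average the effect was larger by day than by night by 0.0895 (SE 0.0213), well above its SE. The 794 genes were chosen from the same libraries and no split recomputed this difference, so noise is less likely but not excluded. With 5 tissue marker scores in the fit the median difference of the 35 genes was 0.233 against 0.261 without them, and 26 kept their call. Without the choroid-rich libraries it was 0.276, although with fewer libraries only 1 of the 35 was still called. Content measured by these scores thus accounts for little of the size in these 35 genes. They were chosen by this same contrast, and the difference over the 794 genes was not refitted with the scores. Other tissue content is therefore not excluded. The same 794 genes were higher at night in homecage mice by 0.123 (SE 0.0151) and in trained mice by 0.0335. The homecage difference less the trained one is the day minus night training effect by definition. A larger homecage than trained difference therefore restates the smaller effect at night and cannot test why it arose. What the levels add is that these genes were not lower at night in trained mice.

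Genes raised by training were also higher at night in homecage mice, which could be tissue content, a chance division of the libraries or time of day. Over all genes the average training effect correlated with the homecage night minus day difference at r = 0.210, and at 0.304 with the marker scores in the fit. The correlation did not fall with the scores, but no split was refitted with them, so other tissue content stays open. Of the 794 raised genes 299 were called higher at night (33.9 expected of independent lists) and 1 lower (19.8 expected), as a shared response of waking and training would give. However, 28 of 100 splits gave a correlation as high as the real 0.210 (highest other 0.559), so a chance division of the libraries is not excluded.

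Lcn2 and Icam1 were high in some trained libraries, which could be blood in the tissue, the library run, choroid plexus content or inflammation in single mice. The highest trained Hbb-bs was 2.60 times the homecage median against 191 times for Lcn2. The homecage median of Lcn2 was 0.0914 CPM, so its ratio is imprecise. More blood of unchanged make-up would raise both genes alike, so it explains little of the rise. Hbb-bs is a haemoglobin gene and does not measure white blood cells, so these stay open as a source. The libraries with more Lcn2 than any homecage library came from 4 library runs, and within runs the correlation with Icam1 was 0.714. With the choroid plexus score the correlation was 0.279 (p = 0.0991). Inflammation or stress in single trained mice remains possible beside the correlation of 0.854 with S100a9, and no record of health was available to test it.

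Calls after redrawing which libraries were trained tell how often chance alone gives as many genes. As many genes as in the real arrangement were called in 1 of 100 splits, the real one itself, at ZT1 (212 genes, highest other 7), ZT5 (126, 1), ZT9 (62, 6), ZT13 (16, 1), ZT17 (5, 1) and for the average (1280, 1). At ZT21 it was 5 of 100 (42 genes, highest other 557), so chance is not excluded for that count. It is for the raised genes shared with other libraries: 24 of the 34 genes raised at ZT21 were also raised at ZT1, and 1 of 100 splits of the ZT21 libraries, the real one, raised as many (24 genes, highest other 8). The day against night difference reached its count in 2 of 100 (35 genes, highest other 769) and the joint interaction in 100 of 100 (0 genes, highest other 55). The list tests gave as many calls in 2 of 100 with the preset correlation (80 calls, highest other 80, median of the others 56), so that most single calls of the preset test are within what redrawn libraries give, and in 1 of 100 with an estimated one (40 calls, highest other 5). After redrawing times within an arm, which ignores the cohorts, the value was 1 of 100 for homecage time of day (867 genes, highest other 93), trained time of day (489, 152), homecage night minus day (1211, 94), homecage rhythm (1641, 68) and trained rhythm (540, 59), and 3 of 100 for trained night minus day (60 genes, highest other 2173).

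Splits that call several times the real number point to a structure of the samples that crosses the arms. At ZT21, 4 splits called more genes than the real one, and in the 3 with most calls the sides differed by at least 0.685 in their dentate granule marker score (log2), against 0.0143 in the real arrangement. Dentate content of the punches may be part of that structure, but other splits differed by up to 0.986 without as many calls.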

How the results depend on the processing

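The settings below were fixed in advance, except the 5 tissue marker scores, the fit without the 18 libraries richest in choroid plexus transcripts and the night minus day results, which were chosen after seeing the data. A count is reported as moved when it changed more than 1.5-fold. Single libraries could not be paired. The replicate numbers only follow the order of the records, and nothing in the labels ties 1 trained library to 1 homecage one. The library runs do group trained with homecage libraries of the same time, but the main fit and the splits ignored them. With run as a covariate 269 genes were called at ZT1 (212 without it) and 159 for day against night (35 without it).

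With RLE factors no count moved, the median log2 fold change over all genes stayed between -0.00597 and 0.00284 (-0.00551 to -0.00091 with TMM), and each of the 246 named gene values kept its call. A prior that is not robust and the cohort covariate for rhythms moved no count either.

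Asking for more than a 1.2-fold change left 13, 11, 6, 4, 0 and 13 genes at ZT1, ZT5, ZT9, ZT13, ZT17 and ZT21 (212, 126, 62, 16, 5 and 42 without it), and 88 of 143 named gene values lost their call. Leaving out the filter tested more genes, which made the adjustment harsher: 120 genes at ZT1, 66 at ZT5, 38 at ZT9, 8 at ZT13, 9 for day against night (35 with the filter), 279 for trained time of day (489), 780 for homecage night minus day (1211), and 1046 and 337 for homecage and trained rhythms (1641 and 540).

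With 3 surrogate variables counts grew to 362 at ZT1, 230 at ZT5, 137 at ZT9, 25 at ZT13, 18 at ZT17, 1989 for the average (1280), 6 for the interaction (0), 130 for day against night, 968 for trained time of day and 236 for trained night minus day (60). With the 5 tissue marker scores they were 478, 280, 156, 26, 21 and 91 at the 6 times, 2139 for the average, 6 for the interaction, 85 for day against night, 1743 and 1044 for homecage and trained time of day (867 and 489), 191 for trained night minus day and 823 for trained rhythms. The cause of the higher counts was not tested.

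Without the choroid-rich libraries, which leaves 3 to 6 per group and so fewer libraries to test with, counts were 19 at ZT1, 51 at ZT5, 11 at ZT9, 9 at ZT13 and 9 at ZT21, with 5 at ZT17, of which 3 were among the 5 called with all libraries. Both ZT13 groups kept all 6 libraries, so the change there came only through libraries of other times in the shared fit. The average had 748, day against night 2, time of day 571 and 138, night minus day 639 and 9, and trained rhythms 127. Of 246 named gene values 84 lost their call. In fits of only the 12 libraries of a time, with fewer degrees of freedom, 28 genes were called at ZT1, 26 at ZT5, 24 at ZT9, 2 at ZT17 and 3 at ZT21.

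DESeq2 called 17 genes at ZT17, 14 for the interaction, 156 for day against night, 817 for trained time of day, 91 for trained night minus day and 876 for trained rhythms, and 11 named gene values gained a call. Library run as a covariate called 159 for day against night, and the cause was not tested. Within cohorts, homecage mice had 842 genes between ZT1 and ZT13, 350 between ZT5 and ZT17 and 73 between ZT9 and ZT21, against 867 in the joint test of time of day. List tests called 80 with the preset and 40 with an estimated correlation.

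Leaving out single libraries gave 112 to 388 genes at ZT1, 56 to 132 at ZT5, 37 to 65 at ZT9, 6 to 13 at ZT13, 2 to 22 at ZT17 and 16 to 97 at ZT21. Only the training effects at single times were refitted this way, not the average, the day against night difference or the rhythms. At ZT1 the count moved without trained replicates 2 (131), 5 (112) and 6 (388). At ZT5 it moved without homecage replicates 3 (67), 4 (63) and 6 (56) and trained replicates 1 (79) and 5 (63), and at ZT9 without homecage replicates 1 (37) and 2 (39). At ZT13 it moved without homecage replicates 2 (10), 4 (6), 5 (9) and 6 (9) and trained replicates 1 (10), 2 (9), 5 (9) and 6 (10). At ZT17 it moved without homecage replicates 1 (22), 2 (3), 3 (2), 4 (2), 5 (3) and 6 (2) and trained replicates 4 (3) and 5 (8), and at ZT21 without homecage replicate 2 (97) and trained replicate 2 (16). Apart from fewer libraries, the cause of these shifts was not tested.

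None of the named gene results that were called changed sign, but values near 0 did. Nr4a1 at ZT17 (-0.16) was 0.0330 with surrogate variables and 0.13 without homecage replicate 1, and -0.295 without homecage replicate 3. On average, Npas2 (0.00) was -0.00578 with surrogate variables and -0.0416 with marker scores, and Cry2 (-0.00) was 0.00657 and 0.00662 in the same fits and 0.0132 without the choroid-rich libraries. Rora (0.00) was -0.000165 with library run and -0.0161 with surrogate variables, and Rorb (-0.01) was 0.00967 with marker scores. For Per2 the day against night difference (0.03) was -0.00284 with surrogate variables. Low counts limit the precision for Egr2 and Lcn2, which lay near or under 1 CPM in most homecage groups.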

Other observations

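The links drawn here were tested after the results were seen, and each explanation is a hypothesis. Over the 794 genes raised by training on average, the mean effect was 0.28 at ZT1, 0.26 at ZT5, 0.22 at ZT9, 0.16 at ZT13, 0.14 at ZT17 and 0.18 at ZT21 (SE 0.0261 each). These genes were chosen by the average of the same 6 effects, so a positive mean is built in and its size tends to be inflated. The values fell from ZT1 to ZT17, and the higher value at ZT21 than at ZT17 was not tested. An order across these times also mixes time with the inferred cohorts. Of the 486 lowered genes 102 were called lower at night in homecage mice (12.1 expected of independent lists) and 3 higher (20.8 expected). Of the raised genes 89.0% had a positive night minus day difference in homecage mice, with a median of 0.11. Genes move together, and 28 of 100 splits gave a correlation across genes as high as the real one. These overlaps were not counted in the splits, so chance is not excluded for them. Fosb, Per2 and Sgk1 were called at each of the 6 times, 4 more genes at 4 times (Ddit4, Errfi1, Fos and the shear-responsive factor Klf2), while 135 genes were called higher and 77 lower at 1 time.

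Arc parted from Sgk1 in its homecage level at night. Homecage Arc was 112 ± 20, 113 ± 31 and 118 ± 24 CPM at ZT1, ZT5 and ZT9 but 189 ± 20, 225 ± 120 and 150 ± 38 CPM at ZT13, ZT17 and ZT21 (n = 6 each), whereas homecage Sgk1 stayed between 68.6 ± 6.4 and 79.3 ± 21 CPM at 5 times and reached 122 ± 20 CPM at ZT9. After training Sgk1 was 135 ± 37 CPM at ZT1, 178 ± 46 at ZT5, 230 ± 51 at ZT9, 156 ± 39 at ZT13, 147 ± 27 at ZT17 and 208 ± 58 at ZT21. The genes overlapped strongly between neighbouring and distant times: 33 genes were higher at ZT5 and ZT9 (0.314 expected by chance), 24 at ZT1 and ZT21 (0.281 expected) and 10 at ZT13 and ZT21 (0.0304 expected).

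Hypothesis: naive mice awake at night may already express part of the program that training evokes by day, which would narrow the contrast at night without a weaker response. The raised genes were higher at night by 0.123 in homecage mice and by 0.0335 in trained mice. The gap between these values is the smaller effect at night itself, so it does not test the hypothesis. In addition, 28 of 100 splits gave a correlation across genes as high as the real one. Mice recorded for activity before sampling, or sleep-deprived homecage mice by day, would separate the explanations.

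Hypothesis: the glucocorticoid-responsive list, called at all 6 times (adjusted p = 0.00025 at ZT17 with an estimated correlation), may reflect handling and novelty as much as memory, and the chaperone lists and the fall of Cirbp and Rbm3 could follow a warmer brain during exploration. No group was handled without training, so learning cannot be told apart from arousal, and the list calls stood at 40 against at most 5 in the other splits. Hormone and temperature records or a handled group exposed to an empty arena would decide.

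Hypothesis: Per1 and Per2 could be raised through the same signals as Sgk1 or through the clock loop, and these data do not decide. Dbp, a target of the clock, lay below the homecage mean in at least 5 of 6 trained libraries at each time except ZT21 (3 of 6), without being called on average. The average effects on Per1 and Per2 were 0.46 and 0.48, and the other clock genes except Cry1 lay between -0.09 and 0.04. In the splits the average called at most 1 gene against 1280 in the real arrangement, so chance is unlikely. A block of glucocorticoid receptor or MAPK signalling before training would test this.

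Whether the response itself was weaker at night stays open. The mean effect over the 794 raised genes was larger by day by 0.0895 (SE 0.0213) and 35 genes differed between day and night, while the joint interaction called 0 genes with edgeR (876 at unadjusted p under 0.05) and 14 with DESeq2. Per1 at ZT17 was above the homecage mean in 6 of 6 trained libraries without being called, and homecage Fos (11.5 ± 6.7 CPM) and Arc varied widely at ZT17.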
